A study of Mus musculus with 7 samples.

How the data were processed

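Bulk RNA sequencing of 7 libraries was analysed, 3 of old and 4 of young mouse HSCs. Per the labels' protocols, bone marrow cells were sorted by flow cytometry, cDNA was made from polyadenylated RNA with the Smart-seq+ protocol, and libraries were made with the Nextera XT kit, which fragments cDNA by tagmentation and does not mark strand. Per the submitters' processing notes, the tools were Trimmomatic, FastQC, STAR and featureCounts and the genome build was mm9. Their versions and settings, the gene annotation and the strand setting are not given in the sources used here. The deposited table holds raw read counts per gene symbol, 1 column per library, which the authors neither scaled nor pooled as far as the values show: they are whole numbers with totals of 22203806 to 32401925 per library. No duplicate removal or molecular identifier is stated, so counts include amplification copies. Reads that match near-identical genes, overlapping genes or pseudogenes could be lost or assigned to one of them, which leaves single values of ribosomal proteins, MHC class I heavy chains, glutathione transferases and Clca1 uncertain. Lpar6 lies inside an intron of Rb1, and counts without strand could mix the 2 genes. Of the 24015 symbols, 22709 matched gene names of a later annotation (GENCODE for GRCm38). Because that build is not mm9, no gene positions are given.

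Each library was placed in its group by its label, and the table columns carry the same names. Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes with too few counts were left out with filterByExpr of edgeR (minimum count 10, minimum total 15), which kept 11506 genes. Libraries were scaled with TMM factors, and old was compared with young by the quasi-likelihood F test of edgeR (glmQLFit and glmQLFTest), 2-sided, with group as the only term and Benjamini-Hochberg adjustment over all tested genes. An adjusted p under 0.05 counted as past the threshold. SE is the absolute log2 fold change divided by the square root of F. Levels are CPM after TMM scaling, as mean ± SD over 3 old or 4 young libraries. Where every library of a group had no count, the fold was computed against 3 counts per library, averaged over the group (0.107 CPM in old and 0.120 CPM in young), and is given as a lower bound.

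The test, the samples, 33 gene lists and the rule for named genes were fixed before the data were examined. The lists came from general knowledge of HSCs, their ageing, lineage programmes, cell cycle, stress and metabolism, and of other cell types of the marrow. Lists with at least 5 tested members were tested with camera of limma (inter-gene correlation preset to 0.01) on log2 CPM with a prior count of 2, adjusted over the 27 lists. Camera compares a list's genes with all other genes. It was repeated with a correlation estimated for each list, and fry was run as a test of the list's genes alone. With fry, 7 lists passed, and 23 passed its mixed version, which asks for change in either direction. Named genes are the 10 highest and the 10 lowest by fold change among those past the threshold with at least 10 CPM in the higher group and groups that do not overlap, leaving out predicted genes and pseudogenes. Only 2 genes were lower. To these came up to 3 tested members of each list with the smallest p, and Selp, Vwf, Clu, Aldh1a1, Nupr1, Slamf1, Flt3, Procr, Cdkn1c, Mki67 and Xist, which made 100 genes. Genes named beyond this rule, among them Cd34, Cd48, Mpo, Elane, Rbl1, Tap2, Cd38, Itgb1 and the other called genes, were chosen after their values were seen or for the checks on other cells.

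The alternatives planned beforehand were DESeq2, limma-voom with and without sample weights, robust dispersions, 3 other scalings, 2 other filters, 2 other thresholds, normalization without ribosomal, mitochondrial and haemoglobin genes, the replicate number as a block, and leaving out each library in turn. Restricting the test to genes with a mean of at least 50 CPM and thinning each library to the smallest total were added after the data were examined. TMM set the median log2 fold change of all tested genes to -0.03. The other scalings set it to -0.05 (DESeq2 size factors), -0.05 (upper quartile) and -0.12 (library size alone). The procedure was tested on simulated counts for the old against young comparison, with 11506 genes of which 200 were changed. It recovered 3 of 50 genes changed 2-fold, 11 of 50 changed 4-fold, 24 of 50 changed 8-fold and 22 of 50 changed 16-fold, with 3 false among 63 calls. Camera with the preset correlation recovered 3 of 3 raised lists and called 0 of 27 unchanged lists, and with an estimated correlation it recovered 2 of 3. The simulated genes varied independently of each other. The 0 false calls therefore do not show how often camera with the preset correlation calls lists whose genes vary together, as ribosomal protein genes did (estimated correlation 0.750). At each fold change simulated, under 50% of the changed genes were recovered, so many differences, large ones included, would not be detected with these libraries.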

Results

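Haematopoietic stem cells (HSCs) were sorted from mouse bone marrow by flow cytometry as lineage-negative Sca-1+ c-Kit+ cells positive for CD150 and negative for CD48, and their polyadenylated RNA was sequenced in bulk. The mice were of the C57BL/6 strain, and the cells were labelled as coming from old or young animals. There were 3 libraries of old HSCs and 4 of young HSCs, and the only comparison was old against young, which asks how transcription in HSCs differs with age. The labels state neither the ages nor whether each library came from a separate mouse. The p-values therefore measure the spread between these samples, part of which may be technical. The deposited table held read counts for 24015 genes, of which 14732 had at least 1 count and 11506 had enough counts to be tested. The old libraries held 28186165, 32401925 and 27369677 counts, and the young libraries 22203806, 22992026, 25904072 and 27146186. Between 10576 (young 1) and 12073 (young 4) genes had a count in a library, and 3108 of the tested genes (27.01%) had no count in at least 1 library. A count of 0 in a library allowed a level of 0.0929 to 0.137 CPM (counts relative to the scaled library total), the worth of 3 counts. The cDNA was amplified and no molecular identifiers were stated, so these limits cover counting error only.

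No pair of libraries agreed within sampling noise, so no library was treated as a second copy of another. Amplified libraries of 1 sample could differ as much, so this does not show that the samples were separate. Across genes, which are not independent replicates, the Pearson correlation of log2 CPM was 0.724 to 0.736 between old libraries, 0.669 to 0.784 between young libraries and 0.623 to 0.723 between the groups. The first principal component held 27.7% of the variance and set young 1 (score 220.9) apart from the 6 other libraries. On this component the old libraries (-90.4 to -70.4) also lay below every young library. Young 3 and young 4 (-18.3 and -24.3) were nearer to the old libraries than to young 1. The second component held 21.5% and set young 2 apart (score 197). Gene levels varied widely between libraries of a group, with a common biological coefficient of variation of 106%.

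Old HSCs held 27 genes at higher and 2 at lower levels than young HSCs. Among the higher genes were Nupr1, a stress-induced nuclear protein, Sult1a1, a phenol sulfotransferase, and Procr, the endothelial protein C receptor and a surface marker of HSCs. Nupr1 averaged 697 ± 135 CPM (SD, n = 3) in old and 31.0 ± 9.52 CPM (SD, n = 4) in young HSCs, a log2 fold change of 4.49 ± 0.30 (SE) with an adjusted p of 8.78e-04 (edgeR). Sult1a1 averaged 1695 ± 226 CPM in old and 65.0 ± 30.002 CPM in young HSCs, a log2 fold change of 4.71 ± 0.39 with an adjusted p of 0.00276. Procr averaged 332 ± 47.9 CPM in old and 49.7 ± 11.7 CPM in young HSCs, 6.68-fold higher in old (adjusted p = 0.00643). The lower genes were Xpo1, the main nuclear export receptor of proteins, and Cd86, a costimulatory ligand of T cells.

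Among the genes higher in old HSCs, those with the largest fitted fold changes had few or no counts in young HSCs. Zg16, a lectin known from zymogen granules, had no count in any young library and 42.8 ± 12.99 CPM in old HSCs, at least 356-fold higher (adjusted p = 0.0457). Gpr183, an oxysterol receptor that guides immune cell migration, averaged 282 ± 141 CPM in old and 0.454 ± 0.885 CPM in young HSCs (adjusted p = 0.0465), and young 2 held 1.78 CPM against 0 to 0.0348 CPM in the other young libraries. Ramp2, a subunit of the adrenomedullin receptor, averaged 235 ± 83.5 and 3.23 ± 2.92 CPM, 72.6-fold higher in old (adjusted p = 0.0281) and 118-fold without young 2. The secreted glutathione peroxidase Gpx3 was 24.1-fold higher (adjusted p = 0.0483; 49.2-fold without young 2), the purine-degrading enzyme Xdh 16.7-fold (adjusted p = 0.00795), Clca1, a calcium-activated chloride channel regulator, 7.13-fold (adjusted p = 0.00795) and the secreted chaperone Clu 6.65-fold (adjusted p = 0.00795). Cd86 had no count in any old library and 32.5 ± 20.8 CPM in young HSCs, at least 303-fold lower in old (adjusted p = 0.0457). Its level in young 2 was 63.6 CPM against 19.4 to 23.7 CPM in the other young libraries. Xpo1 averaged 73.7 ± 12.1 CPM in old and 214 ± 18.98 CPM in young HSCs, a log2 fold change of -1.54 ± 0.23 (adjusted p = 0.0457). Clca1 has a closely similar neighbouring gene, so its reads could be shared with that copy. The symbol is that of the deposited table, and the HSC ageing list counted it as another symbol of Clca3a1. Which gene the table meant could not be checked.

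**Figure D1:**
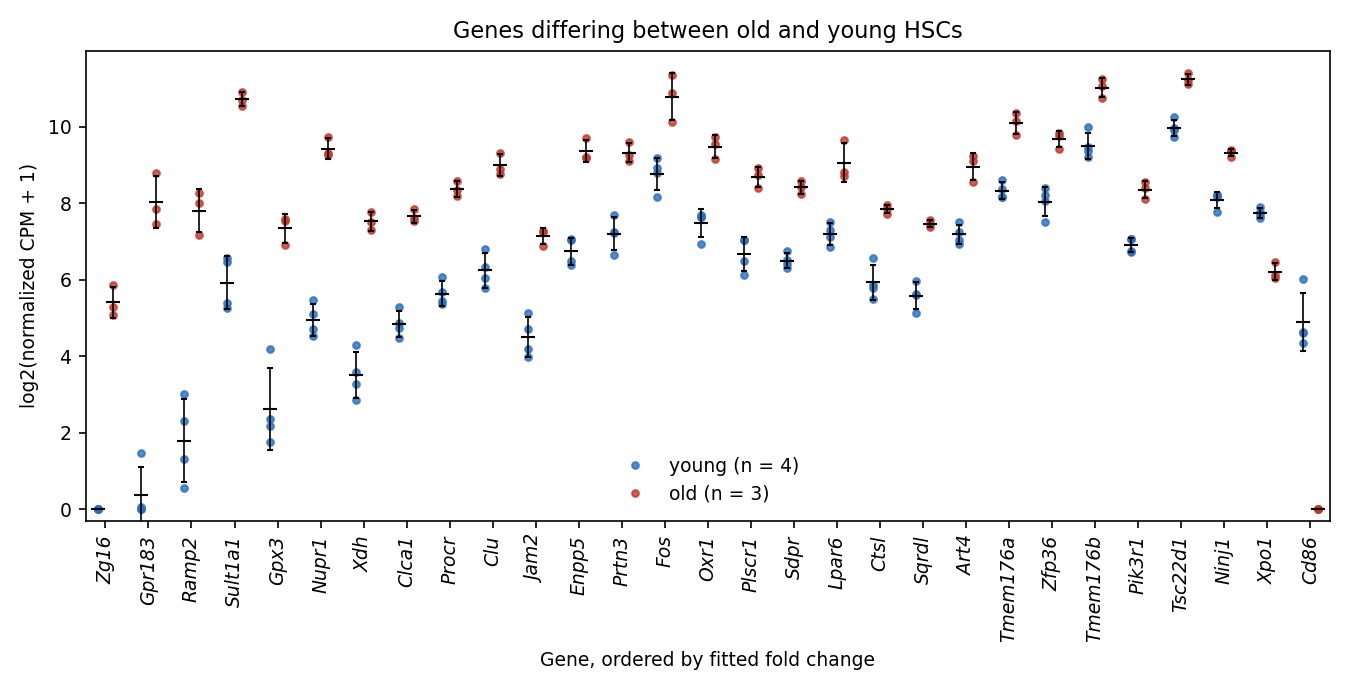
Each point is 1 library's log2(normalized CPM + 1) for each of the 29 genes that differed between old (red, n = 3) and young (blue, n = 4) HSCs, with the mean and SD of each group as bars, ordered by fitted fold change from highest in old to lowest. Every old library lies above every young library for 27 genes and below every young library for Xpo1 and Cd86.

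In all 29 genes the old and young libraries did not overlap. Over all tested genes, 1465 (12.7%) had groups that did not overlap, where chance gives 5.71%. At an unadjusted p under 0.05 there were 1049 genes, 532 higher and 517 lower in old HSCs. The number of calls depended on each library. Fits without 1 library called 2 genes without old 1, 12 without old 2, 2 without old 3, 14 without young 1, 18 without young 2, 10 without young 3 and 11 without young 4. Of these, 2, 10, 2, 11, 14, 10 and 8 were among the 29, and neither Xpo1 nor Cd86 was among them. Nupr1 and Sult1a1 passed in all 7 of these fits. Procr, Enpp5, Clca1, Xdh, Clu and Sdpr passed in 5, failing without old 1 and without old 3 (adjusted p of 0.0503 to 0.102 for Procr, Enpp5, Clca1, Xdh and Clu). Ramp2 passed in 2, without young 1 and without young 2, Gpr183 and Gpx3 in 1, without young 2, and Zg16, Cd86, Xpo1, Fos, Zfp36 and Jam2 in none. All 29 kept their direction in all 7 fits. DESeq2 called 586 genes, 284 higher and 302 lower, including all 29. An edgeR fit restricted to the 4514 genes with a mean of at least 50 CPM, added after the data were examined, called 130 (79 higher and 51 lower).

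Genes tied in general knowledge to the ageing of HSCs were higher as a group in old HSCs. Of the 37 tested members, 12 rose past the threshold over all genes and 27 when adjusted over the list alone, none fell, and 36 had a positive log2 fold change (median 2.24). The 12 were Nupr1, Sult1a1, Clca1, Clu, Ramp2, Zg16, Gpr183, Enpp5, Jam2, Sdpr, Art4 and Tsc22d1. Enpp5, an ectonucleotidase family member, averaged 667 ± 139.7 CPM in old and 109 ± 26.4 CPM in young HSCs (log2 fold change 2.61 ± 0.26, adjusted p = 0.00697). Selp, the adhesion receptor P-selectin, averaged 453 ± 318 CPM in old and 63.1 ± 35.6 CPM in young HSCs, with 116 CPM in young 1 against 42.2 to 50.6 CPM in the other young libraries (adjusted p = 0.106), a log2 fold change of 2.84 that was 2.15 without old 2. The retinaldehyde dehydrogenase Aldh1a1 (log2 fold change 2.24 ± 0.85, adjusted p = 0.417) and Vwf, the platelet adhesion factor (1.12 ± 0.41, adjusted p = 0.390), also missed the threshold over all genes. The list as a whole was higher by camera (adjusted p = 1.09e-27), also with an estimated correlation between its genes (adjusted p = 0.0125), as the only list of which this was true. It passed without each of the 7 libraries.

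Genes that mark HSCs were also higher in old HSCs as a group. Of 36 tested members of the HSC identity list, Procr passed over all genes, 8 were higher and 0 lower when adjusted over the list alone, and 26 had a positive log2 fold change (median 0.56). Pdzk1ip1, a membrane protein enriched in HSCs, averaged 892 ± 272 CPM in old and 226 ± 93.1 CPM in young HSCs (adjusted p = 0.0760). Mllt3, a chromatin reader that maintains HSCs, was 2.88-fold higher (adjusted p = 0.154), and Slamf1, which encodes the CD150 antigen of the sort, 2.37-fold higher (adjusted p = 0.251). As a whole it passed camera (adjusted p = 4.85e-04) but not with an estimated correlation (adjusted p = 0.241), and its median was 0.37 without young 2. Of markers of multipotent progenitors, which DESeq2 called lower in old HSCs (adjusted p = 9.50e-06 for Cd34 and 4.29e-07 for Cd48) and edgeR over all genes did not, Cd34 averaged 109 ± 25.03 CPM in old and 308 ± 70.6 CPM in young HSCs (log2 fold change -1.50, adjusted p = 0.0819). Cd48, whose product the sort excluded, had no count in the old libraries and 12.4 ± 10.1 CPM in the young (adjusted p = 0.159).

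Genes of the cell division cycle were lower in old HSCs as a group, although no single one passed the threshold over all genes and neither list passed with an estimated correlation (adjusted p = 0.147 and 0.219). All 36 tested genes of S phase and DNA replication had a negative log2 fold change (median -1.63), and 22 were lower when adjusted over the list alone. All 36 tested genes of G2 and mitosis had a negative log2 fold change (median -1.82), and 15 were lower when adjusted over the list alone. Mcm5 and Mcm6, subunits of the replicative helicase, averaged 17.0 ± 18.9 and 283 ± 124 CPM in old against 246 ± 133 and 921 ± 368 CPM in young HSCs (adjusted p = 0.140 and 0.152). Cdc6, which loads that helicase, was 4.61-fold lower in old (adjusted p = 0.138). Cdk1, the mitotic kinase, averaged 51.4 ± 20.7 CPM in old and 217 ± 61.6 CPM in young HSCs (log2 fold change -2.08 ± 0.37, adjusted p = 0.0760). Ccna2, the S phase and mitotic cyclin A2, was 5.60-fold lower (adjusted p = 0.0918) and the DNA topoisomerase Top2a 7.64-fold lower (adjusted p = 0.138). Without old 2 the log2 fold change of Top2a was -4.10 against -2.93 with all libraries, and that of Mcm5 -5.32 against -3.85. Mki67, the proliferation marker Ki-67, spread more widely, with 20.1 ± 23.99 CPM in old and 54.9 ± 26.7 CPM in young HSCs (adjusted p = 0.915).

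Both cell cycle lists passed camera, with adjusted p of 1.28e-19 for S phase and DNA replication and 3.37e-19 for G2 and mitosis, but neither with an estimated correlation (adjusted p = 0.147 and 0.219). Among genes with a mean of at least 50 CPM, 7 of 27 S phase genes and 6 of 22 mitotic genes were lower past the threshold, Mcm5, Mcm6, Cdc6, Cdk1, Ccna2 and Top2a among them. The mean log2 CPM of the mitotic genes was 6.31 ± 0.21 in young HSCs (SD, n = 4) and 3.81 ± 1.55 in old HSCs (SD, n = 3), where it ranged from 2.03 to 4.87. None of the progenitor markers Cd34, Cd48 and Flt3 passed in edgeR over all genes, while the edgeR fit to genes with at least 50 CPM called Cd34 lower (adjusted p = 0.0111) and DESeq2 called all 3 lower. Flt3, a cytokine receptor of multipotent progenitors, had no count in the old libraries or in young 1 and averaged 12.99 ± 15.9 CPM in young HSCs, at least 121-fold lower in old (adjusted p = 0.297) and at least 49.1-fold without young 3.

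**Figure D2:**
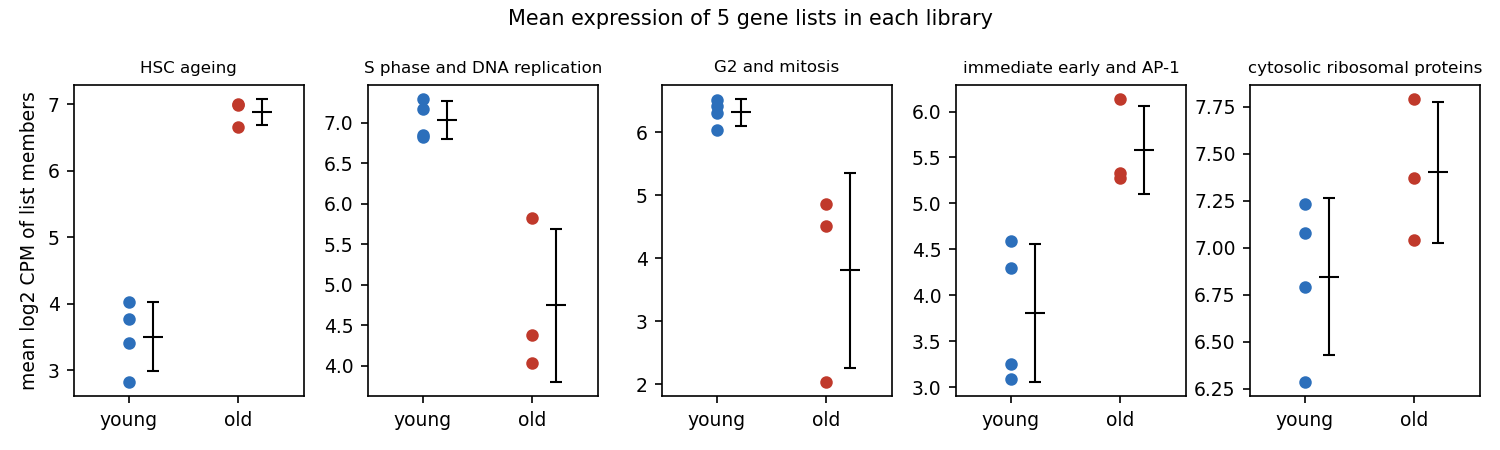
Each point is 1 library's mean log2 CPM over the tested members of a gene list, for 5 lists in young (blue, n = 4) and old (red, n = 3) HSCs, with the mean and SD of each group as bars and a separate vertical axis for each list that does not start at 0. The old libraries lie at 6.67 to 7.01 for HSC ageing genes against 2.82 to 4.02 in young, and at 2.03 to 4.87 for G2 and mitosis genes against 6.03 to 6.51 in young, while the ranges overlap for ribosomal protein genes.

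The list of quiescence and cyclin-dependent kinase inhibitor genes was slightly higher as a group in old HSCs. It also holds the cyclins and kinases Ccnd1, Ccnd2, Ccnd3, Cdk4 and Cdk6, which drive the cycle, so it does not stand for quiescence alone. Btg2, Egr1, Nr4a1 and Nr4a2 belong to the immediate early list too, so the lists are not independent. No member of the 30 tested passed over all genes, and 21 had a positive log2 fold change (median 0.38). Adjusted over the list alone, 4 were higher, and 1, Rbl1, a retinoblastoma-family repressor, was lower (log2 fold change -1.20). The antiproliferative gene Btg2 averaged 208 ± 79.2 CPM in old and 45.0 ± 16.03 CPM in young HSCs (adjusted p = 0.0760), and the imprinted growth suppressor Ndn 205 ± 32.6 and 78.9 ± 35.7 CPM (adjusted p = 0.191). Cdkn1c, which encodes the inhibitor p57, averaged 96.8 ± 21.3 and 49.3 ± 21.2 CPM (adjusted p = 0.483). The list passed camera (adjusted p = 0.0211) but not with an estimated correlation (adjusted p = 0.341) or with fry (adjusted p = 0.0979). Nor did it pass without old 3 (adjusted p = 0.0729) or without young 2 (adjusted p = 0.0516), and its median was 0.57 without young 3 and 0.63 without young 4. The mean log2 CPM of the list was 3.56 and 3.62 in young 1 and young 2. In young 3 and young 4 it was 4.83 and 4.84, close to the 4.99 to 5.11 of the old libraries. The difference between the groups thus came mostly from young 1 and young 2.

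Immediate early genes, which cells transcribe within minutes of a stimulus, were higher in old HSCs. Zfp36 and Fos passed over all genes, 9 of 28 tested members were higher and 0 lower when adjusted over the list alone, and 25 had a positive log2 fold change (median 1.12). Zfp36, which promotes the decay of cytokine messenger RNAs, averaged 819.9 ± 117 CPM in old and 269 ± 65.9 CPM in young HSCs (log2 fold change 1.61 ± 0.24, adjusted p = 0.0457). Fos, a subunit of the transcription factor AP-1, averaged 1863 ± 741 and 448 ± 121 CPM (log2 fold change 2.06 ± 0.33, adjusted p = 0.0483). Both calls were lost without any 1 of the 7 libraries, at adjusted p of 0.0671 to 0.253 for Zfp36 and 0.0519 to 0.253 for Fos. Ier3 was 4.31-fold higher (adjusted p = 0.0760), and the zinc finger factor Egr1 2.30-fold higher (adjusted p = 0.191). Camera called the list higher (adjusted p = 6.55e-10), but not with an estimated correlation (adjusted p = 0.219).

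Genes of cytosolic ribosomal proteins were slightly higher as a group in old HSCs. Of 80 tested, 77 had a positive log2 fold change (median 0.57) and none passed, either over all genes or when adjusted over the list alone. Rpl13 averaged 1620.0 ± 420.0 CPM in old and 754 ± 186 CPM in young HSCs (adjusted p = 0.164), Rps3a1 786 ± 163 and 425 ± 66.7 CPM (adjusted p = 0.181) and Rpl10 482 ± 139.5 and 255 ± 47.6 CPM (adjusted p = 0.213). Ribosomal protein genes have many processed pseudogenes, so single values are uncertain. The list passed camera (adjusted p = 1.58e-09). Its genes varied together, with an estimated correlation of 0.750, and with that correlation the list did not pass (adjusted p = 0.554). Nor did it pass fry (adjusted p = 0.157).

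Genes of autophagy and the lysosome had a small positive median log2 fold change in old HSCs, with 1 gene call among 38 tested. The mean difference in log2 CPM of the list was only 0.07. Its library means in old HSCs (6.07 to 6.37) lay within the range of the young (5.83 to 6.40). Ctsl, the lysosomal protease cathepsin L, averaged 229.5 ± 18.0 CPM in old and 62.3 ± 21.5 CPM in young HSCs (log2 fold change 1.88 ± 0.30, adjusted p = 0.0483), and passed in 1 of the 7 fits without a library, that without young 1. Cd63, a tetraspanin of late endosomes, was higher when adjusted over the list alone, together with Ctsl, with 1838 ± 70.0 and 903 ± 259 CPM (adjusted p over all genes 0.159). The cholesterol-binding protein Npc2 averaged 229.7 ± 26.0 and 132 ± 14.0 CPM (adjusted p = 0.199). Of the list, 25 members had a positive log2 fold change (median 0.28). It passed camera (adjusted p = 0.0323) but not with an estimated correlation (adjusted p = 0.241), without scaling beyond library size (adjusted p = 0.0502), or without old 1, old 2, old 3, young 1 or young 3 (adjusted p = 0.0567, 0.115, 0.148, 0.0514 and 0.0531).

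Genes of antigen presentation by MHC class I were higher in old HSCs as a group, with no gene call over all genes. Of 18 tested members, 15 had a positive log2 fold change (median 0.48). Adjusted over the list alone, 4 were higher, and 1, the peptide transporter subunit Tap2, was lower (log2 fold change -2.28). B2m, the invariant light chain, averaged 5084 ± 2684 CPM in old and 1736 ± 622 CPM in young HSCs (adjusted p = 0.176), the nonclassical heavy chain H2-T23 935 ± 347 and 371 ± 112 CPM (adjusted p = 0.162), and the classical heavy chain H2-D1 2032 ± 431 and 1007 ± 350.3 CPM (adjusted p = 0.234). Class I heavy chain genes are similar in sequence, so their reads could be divided uncertainly. Camera called these genes higher (adjusted p = 0.0133), but not with an estimated correlation (adjusted p = 0.341) or without old 1 (adjusted p = 0.0860). The list did not pass fry (adjusted p = 0.0979).

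The MHC class II list was higher too, with 9 of 10 tested members at a positive log2 fold change (median 0.95) and none past the threshold over all genes or when adjusted over the list alone. Its regulator Ciita had no count in any young library and 1.26 ± 0.994 CPM in old HSCs, at least 10.4-fold higher (adjusted p = 0.276) and at least 5.88-fold without old 2. H2-Eb1 averaged 71.3 ± 77.5 CPM in old and 4.42 ± 3.82 CPM in young HSCs (adjusted p = 0.314), and H2-DMb1 195 ± 50.9 and 115 ± 30.7 CPM (adjusted p = 0.444). The list passed camera (adjusted p = 0.0171) but not with an estimated correlation (adjusted p = 0.253), without old 1 (adjusted p = 0.168, median 0.19), without young 4 (adjusted p = 0.0558) or with every library thinned to the smallest, a setting added after the data were examined (adjusted p = 0.0913). It did not pass fry either (adjusted p = 0.144). Its mean log2 CPM was 6.36 in old 1 against 4.83 and 5.25 in the other old libraries, so the size of the median rested on old 1.

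Lists of epigenetic regulators and of DNA damage response and repair were called lower in old HSCs by camera, although the library means of both overlapped between the groups. Neither held a gene call, over all genes or when adjusted over the list alone. Of 37 tested epigenetic regulators, 30 had a negative log2 fold change (median -0.47). The heterochromatin protein Cbx5 averaged 159.6 ± 50.4 CPM in old and 296 ± 29.8 CPM in young HSCs (adjusted p = 0.249), and the deacetylase Hdac1 154 ± 28.0 and 254 ± 65.8 CPM (adjusted p = 0.381), with 352 CPM in young 1 against 208 to 228 CPM in the other young libraries. The Polycomb protein Cbx2 had no count in the old libraries and 4.16 ± 3.74 CPM in the young, at least 38.8-fold lower in old (adjusted p = 0.351). This list passed camera (adjusted p = 0.00127) but not with an estimated correlation (adjusted p = 0.226) or with fry (adjusted p = 0.0722). Its median was -0.82 without old 2. The mean log2 CPM of the epigenetic list was 3.74 to 4.84 in old and 4.66 to 5.51 in young libraries.

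Of 40 tested genes of DNA damage response and repair, 27 had a negative log2 fold change (median -0.51). The mean log2 CPM of the list was 3.76 and 3.87 in young 1 and young 2, within or near the old range of 3.76 to 4.46. Only young 3 and young 4 lay above the old libraries (5.05 and 5.02), and the mean difference was -0.30. The histone variant H2afx averaged 127 ± 35.4 CPM in old and 273 ± 57.2 CPM in young HSCs (adjusted p = 0.188). The translesion polymerase Rev1 was 5.24-fold lower (adjusted p = 0.242) and the poly(ADP-ribose) polymerase Parp1 4.93-fold lower (adjusted p = 0.304). The list passed camera (adjusted p = 0.0320) but not with an estimated correlation (adjusted p = 0.429) or with fry (adjusted p = 0.182). It also failed without old 1, old 3, young 3 or young 4 (adjusted p = 0.0510, 0.0797, 0.151 and 0.112).

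**Figure D3:**
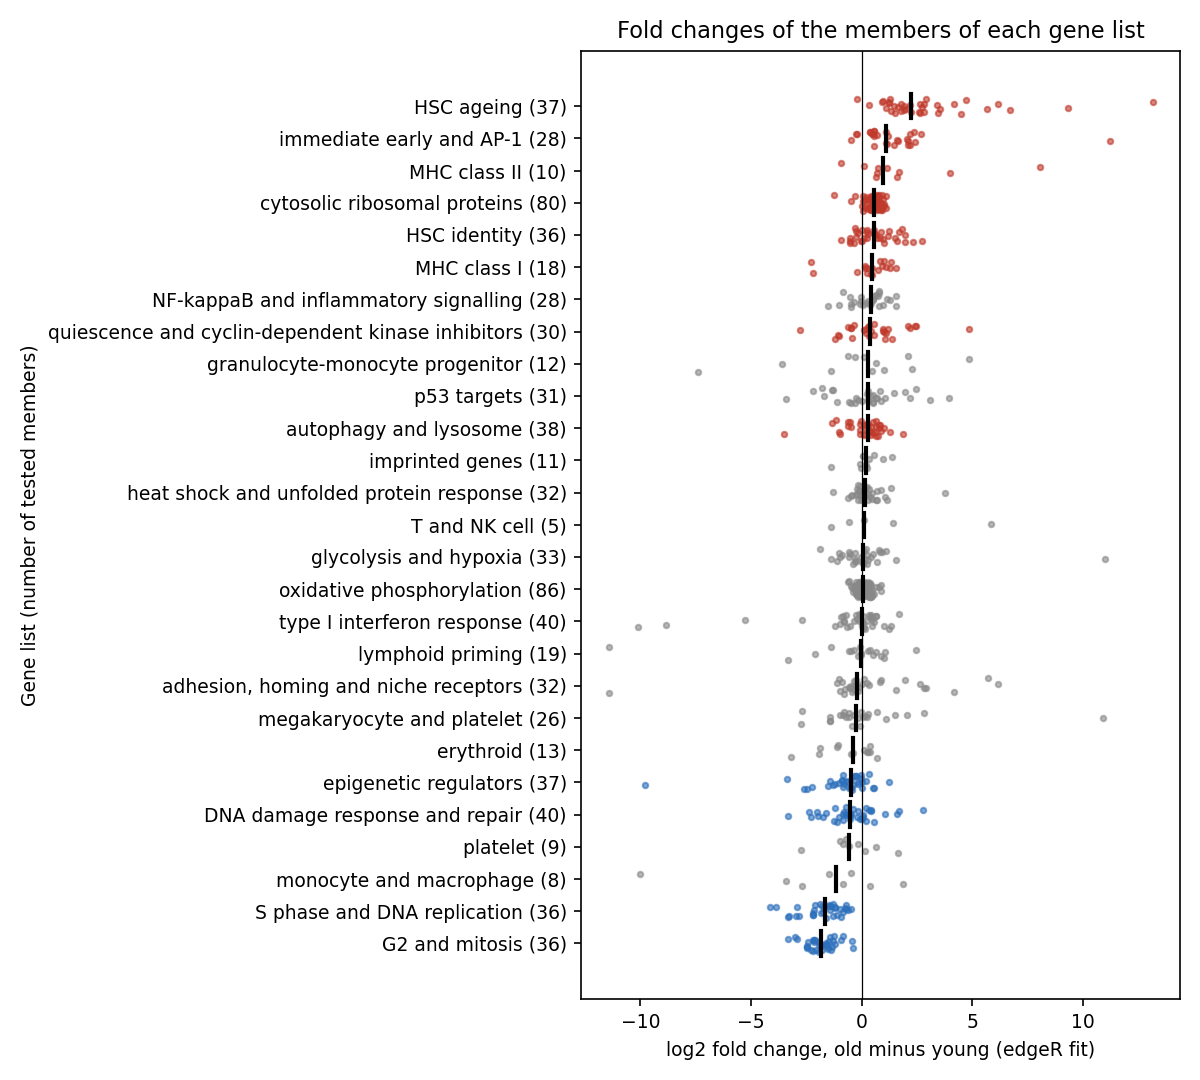
Each point is the log2 fold change, old minus young, of 1 tested member of a gene list, for the 27 lists tested, with the number of tested members in brackets and the median of each list as a black bar. Lists past the camera threshold are red where higher in old (8 lists, medians 0.28 to 2.24), blue where lower (4 lists, medians -1.82 to -0.47) and grey where not past it, and points beyond 8 on either side are genes with no or hardly any counts in one group.

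Of the 27 lists tested, 12 passed camera, 1 of them, HSC ageing, also with an estimated correlation, and the 15 others did not. Setting genes with an empty group to their bound left each list median as given. Lineage lists were among those that did not pass. For the megakaryocyte and platelet list, 10 of 26 tested members had a positive log2 fold change (median -0.25, adjusted p = 0.840). Adjusted over the list alone, Selp and Alox12 were higher. Alox12, the platelet 12-lipoxygenase, had no count in the young libraries and 9.11 ± 1.12 CPM in old HSCs, at least 75.8-fold higher (adjusted p = 0.165), and the platelet integrin Itga2b averaged 7.19 ± 3.28 CPM in old and 47.8 ± 28.4 CPM in young HSCs (adjusted p = 0.290). For lymphoid priming, 8 of 19 were positive (median -0.04, adjusted p = 0.848). Of its members, Sox4 averaged 1.05 ± 0.663 CPM in old and 10.7 ± 2.21 CPM in young HSCs (adjusted p = 0.489), and Mef2c 285 ± 30.9 and 180.2 ± 64.8 CPM (adjusted p = 0.614). For erythroid genes, 6 of 13 were positive (median -0.37, adjusted p = 0.485). The erythroid factor Gata1 averaged 12.5 ± 14.6 CPM in old and 115 ± 39.4 CPM in young HSCs (adjusted p = 0.499). Its levels were 28.5 CPM in old 1, 9.04 CPM in old 2 and 0 in old 3, so the old mean rested mostly on old 1. Carbonic anhydrase Car2 averaged 8313 ± 1593 and 5165 ± 1344 CPM (adjusted p = 0.371) and Nfe2 1607 ± 143 and 1228 ± 68.1 CPM (adjusted p = 0.545). No lymphoid or erythroid gene passed when adjusted over the list alone.

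The granulocyte-monocyte progenitor list held 1 call among 12 tested members. Prtn3, the granule protease proteinase 3, averaged 645 ± 116 CPM in old and 151 ± 43.8 CPM in young HSCs (log2 fold change 2.10 ± 0.27, adjusted p = 0.0242), and passed without young 1 or young 3 but not without any of the other libraries (adjusted p = 0.0504 to 0.141). Adjusted over the list alone, 3 were higher and 0 lower. These were Prtn3, Cd63 and Gstm1, a glutathione transferase from a family of similar genes, at 1428 ± 196 CPM in old and 295 ± 137 CPM in young HSCs (adjusted p over all genes 0.0760). Of other proteins of these granules, Ctsg had no count in any library. Mpo had none in the old libraries and 24.6 and 7.90 CPM in young 1 and young 2, and Elane had counts in old 1 (9.33 CPM) and young 3 (7.01 CPM). The list did not pass (median 0.29, adjusted p = 0.307).

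Among signalling and stress lists, type I interferon response genes did not pass (40 tested, 0 past adjusted over the list alone, adjusted p = 0.582). Their median log2 fold change was 0.02, while their mean difference in log2 CPM was -0.35 and the test pointed to lower. Ifitm1 averaged 1661 ± 278 CPM in old and 658 ± 286 CPM in young HSCs (adjusted p = 0.166), Gbp2 172 ± 51.7 and 72.7 ± 31.1 CPM (adjusted p = 0.300), and Ifi27l2a had no count in the old libraries, at least 48.8-fold lower in old (adjusted p = 0.191). The list of NF-kappaB and inflammatory signalling did not pass (28 tested, 0 past adjusted over the list alone, median 0.41, adjusted p = 0.0889), but passed fry, which asks whether a list's genes move one way on balance (adjusted p = 0.0332). Its inhibitor Nfkbia averaged 449.9 ± 162 CPM in old and 155 ± 82.2 CPM in young HSCs (adjusted p = 0.197), Irak3 194 ± 61.3 and 112 ± 24.4 CPM (adjusted p = 0.407) and Bcl3 47.8 ± 15.3 and 19.5 ± 3.10 CPM (adjusted p = 0.498). Targets of p53 did not pass (31 tested, median 0.29, adjusted p = 0.181), with Btg2, Plk2 and Sesn1 higher when adjusted over the list alone. The kinase Plk2 averaged 439.8 ± 271 CPM in old and 28.0 ± 19.1 CPM in young HSCs (adjusted p = 0.171; log2 fold change 3.97, and 3.36 without old 3) and Sesn1 563 ± 62.8 and 271 ± 87.4 CPM (adjusted p = 0.204). Heat shock and unfolded protein genes did not pass (32 tested, median 0.15, adjusted p = 0.105), and the chaperone Dnajb9 was higher when adjusted over the list alone (194 ± 31.8 and 94.0 ± 10.2 CPM, adjusted p over all genes 0.150). Xbp1 was 1.82-fold higher (adjusted p = 0.207) and Hsp90aa1 1.55-fold higher (adjusted p = 0.356).

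Metabolic, imprinted and adhesion lists did not pass either. Genes of oxidative phosphorylation lay near 0 (86 tested, 0 past adjusted over the list alone, median 0.05, adjusted p = 0.485), with Sdhc (log2 fold change 0.63 ± 0.26), Ndufaf3 (0.87 ± 0.40) and Ndufa11 (0.79 ± 0.37) at adjusted p of 0.469, 0.578 and 0.578. For glycolysis and hypoxia (33 tested, median 0.08, adjusted p = 0.302), 3 genes were higher when adjusted over the list alone. The glycolytic enzymes Aldoa and Ldha were 1.74-fold and 1.89-fold higher (adjusted p over all genes 0.163 and 0.166), and Eno2 had no count in the young libraries and 9.68 ± 12.04 CPM in old HSCs, at least 80.5-fold higher (adjusted p = 0.193) and at least 22.9-fold without old 3. Imprinted genes (11 tested, median 0.21, adjusted p = 0.184) held Ndn as higher when adjusted over the list alone, and Peg12 averaged 16.1 ± 12.4 CPM in old and 42.4 ± 42.1 CPM in young HSCs, with 105 CPM in young 1 against 13.2 to 28.2 CPM in the other young libraries (adjusted p = 0.777). In the list of adhesion, homing and niche receptors (32 tested, adjusted p = 0.307), Ramp2 and the junctional protein Jam2 rose past the threshold over all genes. Jam2 averaged 141 ± 20.02 CPM in old and 22.9 ± 8.69 CPM in young HSCs (log2 fold change 2.62 ± 0.39, adjusted p = 0.0457). Adjusted over that list alone, 4 were higher, Selp and Cd38 with these, and the integrin Itgb1 was lower. The median log2 fold change of the adhesion list was -0.21, while its mean difference in log2 CPM was 0.73 and the test pointed to higher.

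Markers of other cell types were checked, since a sort can carry them. Of these lists only MHC class II, which also marks antigen-presenting cells, passed camera (adjusted p = 0.0171) but not with an estimated correlation (adjusted p = 0.253), without old 1 (adjusted p = 0.168) or without young 4 (adjusted p = 0.0558). Platelet genes (9 tested, median -0.56, adjusted p = 0.848) went both ways, and adjusted over the list alone Gng11 was higher (474 ± 63.0 and 149.5 ± 49.6 CPM) and Itga2b lower, while Nrgn averaged 229 ± 54.4 and 146 ± 41.2 CPM. Monocyte and macrophage genes (8 tested, median -1.16, adjusted p = 0.312) included Lyz2 at 1200.2 ± 284 CPM in old and 909 ± 259 CPM in young HSCs, Cd68 at 14.2 ± 6.51 and 39.7 ± 19.8 CPM, and C1qa with no count in the old libraries and 4.86 ± 5.54 CPM in the young. T and NK cell genes (5 tested, median 0.13, adjusted p = 0.485) included Klrb1c at 178 ± 64.9 CPM in old and 3.04 ± 6.08 CPM in young HSCs (adjusted p = 0.324), Nkg7 at 70.8 ± 43.9 and 184 ± 137 CPM, and Cd247 at 5.26 ± 1.41 and 1.93 ± 2.50 CPM. No monocyte or T and NK cell gene passed when adjusted over the list alone.

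The remaining marker lists had under 5 tested members and were not tested as lists, and none of their members passed over all genes or when adjusted over the list alone. For mature neutrophils, S100a8 and Ngp averaged 0.237 ± 0.411 and 4.11 ± 6.49 CPM in old and 1.31 ± 1.34 and 5.22 ± 8.18 CPM in young HSCs, and Pglyrp1 46.3 ± 23.5 and 16.3 ± 4.92 CPM. Cd79b, the only B cell gene tested, averaged 151 ± 67.2 CPM in old and 144 ± 27.9 CPM in young HSCs, and the sign of its fold change turned under 1 of 3 other scalings. For mast cells and basophils, Cpa3 averaged 24.7 ± 12.6 and 3.28 ± 4.86 CPM, Fcer1a 14.1 ± 14.0 and 2.12 ± 4.25 CPM and Il4 8.10 ± 2.50 and 7.56 ± 1.81 CPM. For endothelial and stromal cells, Emcn averaged 96.6 ± 18.6 and 58.8 ± 8.59 CPM, Kdr 2.74 ± 2.37 and 2.02 ± 3.95 CPM and Plvap 1.27 ± 1.37 and 1.55 ± 3.06 CPM. Xist, the RNA that silences one X chromosome in females, had counts in all 7 libraries, at 65.7 ± 35.8 CPM in old and 111 ± 47.7 CPM in young HSCs (adjusted p = 0.760). Its antisense partner Tsix averaged 3.59 ± 1.68 and 1.15 ± 1.95 CPM, and without strand the reads of these 2 genes cannot be told apart. The Y-linked genes Ddx3y, Eif2s3y and Kdm5d had no count in any library, and Uty had 1 count in all. The table held no mitochondrially encoded gene, so these were not analysed here.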

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

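The following values come from young HSCs, where 1 of 4 libraries lay far from the other 3 by Dixon's test. This held for 11 of the 100 named genes. A chance rate of about 1 in 20 holds for normally distributed values, which CPM near 0 are not. Where 3 libraries lie at or near 0, almost any level in the other is flagged, as for Klrb1c, Fcer1a, Kdr, Plvap and Gpr183. Over all tested genes an outlying young library was found for 1159 of 11506 (10.1%), in young 1 for 263 genes, in young 2 for 302, in young 3 for 324 and in young 4 for 270. The named genes thus stood close to the rate of all genes. The 3 old libraries were too few for this test.

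Young 2 stood apart in 4 genes. It held Gpr183 at 1.78 CPM against 0 to 0.0348 CPM in the other young libraries, Gpx3 at 17.3 CPM against 2.37 to 4.11 CPM, and Cd86 at 63.6 CPM against 19.4 to 23.7 CPM. It held Tsix at 4.06 CPM against 0.0348 to 0.397 CPM. Without young 2, Gpr183 had an adjusted p of 8.76e-04 and Gpx3 of 0.00395 in edgeR, below the values with all libraries (0.0465 and 0.0483), while Cd86 had 0.0911 against 0.0457. Over the 7 fits without a library, adjusted p ranged from 8.76e-04 to 0.279 for Gpr183, 0.00395 to 0.253 for Gpx3 and 0.0911 to 0.173 for Cd86.

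Young 1 held Selp at 116 CPM against 42.2 to 50.6 CPM in the other young libraries, Hdac1 at 352 CPM against 208 to 228 CPM, and Peg12 at 105 CPM against 13.2 to 28.2 CPM. Young 4 held Klrb1c at 12.2 CPM and Fcer1a at 8.50 CPM, with no count of either in the other young libraries, and Kdr at 7.94 CPM against 0 to 0.131 CPM. Young 3 held Plvap at 6.14 CPM against 0 to 0.0457 CPM.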

How the results depend on the processing

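The fit to genes with a mean of at least 50 CPM and the thinning to the smallest library were chosen after the data were examined. The direction of all 29 genes and 12 lists past the threshold was the same under every alternative that tested them, and no call reversed. With all 7 libraries edgeR called 27 genes higher and 2 lower, 29 in all. DESeq2 called 284 higher and 302 lower (586), limma-voom 49 and 1 (50), limma-voom with sample weights 82 and 10 (92), and library size alone 15 and 1 (16). DESeq2 kept all 29 genes, limma-voom 25, weighted limma-voom 27 and library size alone 16. Of the 586 genes of DESeq2, 135 had a group with no count in any library and 325 a mean of at least 50 CPM. The edgeR fit to the 4514 genes with at least 50 CPM called 79 and 51 (130), all of which DESeq2 also called, and 27 of the 29. An adjusted p under 0.01 left 7 higher, 0 lower and 7 in all (517 were lower at an unadjusted p under 0.05). The cause of these differences between tests and scalings was not tested. Leaving out 1 library gave 2 to 16 genes higher, 0 to 2 lower and 2 to 18 in all, from fewer samples. Where edgeR called 0 genes lower, without old 1, old 3, young 1, young 3 or young 4, there were 434, 461, 436, 357 and 393 lower at an unadjusted p under 0.05. The other settings stayed within 1.5 times, with 22 to 38 genes higher and 24 to 41 in all. Thinning to the smallest library kept all 29, so these calls did not depend on the unequal totals of the libraries. The totals ran only from 22203806 to 32401925, so thinning does not show how depth in general bears on the count.

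Old and young libraries with the same number did not deviate together (correlations 0.025, -0.074 and -0.014). This gave no sign that the numbers pair the samples, but so few libraries cannot rule pairing out. The replicate number as a block gave 0 genes higher, 0 lower and 0 in all in edgeR, with 694 genes at an unadjusted p under 0.05 (403 higher, 291 lower), a smallest adjusted p of 0.137 and few residual degrees of freedom. With this block 9 lists passed, without DNA damage response, autophagy and MHC class II. Not every library correlated best with its own number.

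Of the lists, 12 passed camera, 1 with an estimated correlation and 7 with fry, of which 6 were among the 12. Quiescence, DNA damage response, ribosomal proteins, MHC class I, MHC class II and epigenetic regulators passed camera but failed fry. The other settings gave 8 to 12 lists. HSC ageing passed in all 14 alternatives, and HSC identity, both cell cycle lists and immediate early genes in 13, failing with the estimated correlation. Ribosomal proteins and epigenetic regulators passed in 12, failing with the estimated correlation and with fry. MHC class I passed in 11, quiescence in 10, MHC class II in 8, DNA damage response in 7 and autophagy in 6. Among values past no threshold in either fit, 19 values of 4 named genes and 11 list directions changed sign, and 54 values of named genes were missing because the gene was filtered out. Alternatives for normalized values were not run, since the table holds counts.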

Other observations

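The genes described first were chosen after their values were seen, as were the test on Prtn3, the thinning of libraries and the restriction to genes with a mean of at least 50 CPM. Of phospholipid scramblases, glutathione enzymes and metallothioneins, Plscr1, Plscr2, Plscr4, Gstm1, Gstm2, Gpx3 and Mt1 were among the genes higher in old HSCs, without a test of these families as groups. Plscr2, Gstm2 and Mt1 belong to the HSC ageing list and Gstm1 to the granulocyte-monocyte progenitor list. Their adjusted p comes from the edgeR fit to genes with a mean of at least 50 CPM, and none but Plscr1 and Gpx3 passed over all 11506 genes. Plscr2 averaged 501 ± 98.7 CPM in old and 4.79 ± 4.14 CPM in young HSCs (adjusted p = 0.00377), Plscr4 242 ± 40.7 and 67.8 ± 23.1 CPM (adjusted p = 0.0111) and Plscr1 414 ± 73.7 and 104 ± 31.2 CPM (adjusted p = 0.00343). Of the glutathione enzymes, Gstm1 had an adjusted p of 0.00747, Gstm2 of 0.0303 (176 ± 36.4 and 38.4 ± 17.6 CPM) and Gpx3 of 0.00401. Another glutathione transferase, Gstz1, went the other way and was lower by DESeq2 (log2 fold change -1.11, adjusted p = 0.0178). Metallothionein Mt1 averaged 149 ± 38.8 and 13.9 ± 9.51 CPM (adjusted p = 0.0111). The lipid carrier Apoe averaged 2321 ± 222 and 1109 ± 139.5 CPM (adjusted p = 0.0110). In each of these genes but Gstz1 every old library was above every young one.

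In the same fit, the enzymes Phgdh, Shmt1 and Mthfd1 were among the genes lower in old HSCs. Phgdh, which starts serine synthesis, averaged 79.9 ± 18.2 CPM in old and 237 ± 89.5 CPM in young HSCs (adjusted p = 0.0392). The folate enzymes Shmt1 and Mthfd1 averaged 33.7 ± 16.7 and 15.9 ± 9.39 CPM in old against 138 ± 37.7 and 116 ± 75.1 CPM in young (adjusted p = 0.0279 and 0.0438). Kpna2, an importin subunit, averaged 49.9 ± 18.6 and 154 ± 36.6 CPM (adjusted p = 0.0337), beside the export receptor Xpo1 (adjusted p = 0.00985). No group of these genes was tested for enrichment.

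Chance was weighed for the counts by the 35 splits of the 7 libraries into 3 and 4. Of these, 1, the real one, gave as many genes higher (27, highest other 0), lower (2, highest other 0) and differing (29, highest other 0). A share of 1 in 35 is the smallest this test can reach, so chance was made less likely but not excluded. Every other split mixed old and young libraries, which can widen the spread within groups and leave few calls. The 2 lower genes, Xpo1 and Cd86, passed in no fit without 1 library. For lists, 1 of 35 splits, the real one, gave as many as 12, and the other splits gave 0 to 9. Splits with only 1 old library gave up to 5, so camera with the preset correlation called lists in mixed groups too.

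The lower cell cycle genes of old HSCs had a median log2 fold change of -1.72 with every library thinned to the smallest total, as without thinning. Counts were scaled to library size in both fits, so thinning could hardly move this median and does not decide on depth. Each old library held more counts (27369677 or more) than any young one (27146186 or fewer), so a lack of reads in old does not explain it. The median of the cell cycle genes lay between -2.11 and -1.41 whichever library was left out, which argues against 1 unusual library. Multipotent progenitors in the young sorts remain open: the median of Cd34, Cd48 and Flt3 was -6.86, with empty groups set to 3 counts per library. None of them passed in edgeR over all genes, but DESeq2 called all 3 lower (adjusted p = 9.50e-06, 4.29e-07 and 7.62e-04), and the fit to genes with at least 50 CPM called Cd34 (adjusted p = 0.0111). More progenitors among the sorted young cells and less cycling of old HSCs cannot be told apart here, although the gate excluded CD48-positive cells, and age itself was not tested against any other difference between the groups.

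The higher immediate early genes were weighed as well. Their median log2 fold change lay between 1.04 and 1.35 whichever library was left out, against 1.12 with all, which argues against 1 unusual library. Stress of handling may raise such genes together with inducible chaperones. Of these, Dnajb1, Hsph1 and Hspa8 had a median of 0.28 (0.28, -0.14 and 0.39), and camera did not call them as a group, whereas Hspa1a and Hspa1b had too few counts to be tested. This neither met nor ruled out the prediction, so handling and age cannot be told apart.

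For Prtn3, granulocyte progenitors in the old sorts were weighed, cells that the gate on lineage and stem cell antigens would remove. Such cells would bring Mpo, Elane and Ctsg at levels like that of Prtn3, but together these reached at most 1.503% of the rise of Prtn3 in any old library, with Mpo and Ctsg at 0 and Elane at 3.11 CPM on average. Other genes of these cells went with the explanation, Gfi1 at 13.5 ± 12.2 and 0.464 ± 0.602 CPM in old and young, Ctsc at 639 ± 51.5 and 393 ± 77.6 CPM and Srgn at 1420 ± 474 and 745 ± 162 CPM (Ctsc and Srgn called by DESeq2), while Ms4a3 averaged 1.15 and 1.41 CPM. Ctsg had no count in any library, young ones included, so its absence does not bear on the old sorts. Mpo at 0 and Elane far below the rise of Prtn3 argue against granulocyte progenitors as its source. This rests on a test chosen after the values were seen. Other explanations, among them a difference with age in the HSCs, were not tested.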
